A study of Caenorhabditis elegans with 6 samples.

How the data were processed

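Total RNA of wild-type N2 *C. elegans* was measured in 6 samples, 3 of fed L1 larvae and 3 of mixed embryos, as biotin-labelled cRNA from 8 µg of RNA on 1-channel Affymetrix arrays, per the labels. The deposited values are on the log2 scale, 1 per probe set and array. They were made with RMA, which corrects background, normalizes between arrays and summarises probes, per the submitters' processing notes, and the RMA version is not given in the sources used here. Per the labels, the embryo arrays were a re-analysis of arrays of an earlier series, and whether all 6 arrays were normalized together is not given in the sources used here. In the values, sorted columns differed from their common mean by at most 0.105 to 0.176, and array medians were 6.08 to 6.10 for L1 and up to 6.04 for embryos. RMA equalises overall distributions, so a general rise or fall in RNA per animal would not be seen, and low values are compressed.

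Of 22625 probe sets, 77 control probe sets were left out of all tests and 22548 were tested. Gene symbols came from the array's platform annotation. A total of 20766 probe sets named 1 gene, 887 named several and 895 named none, and only the first kind was used for genes. For each of 17118 genes the probe set with the highest mean over all arrays was used. Among 2981 genes with more than 1 probe set, the probe sets of 495 differed in sign and those of 478 were over 1 log2 unit apart. Among named genes, 32 had several probe sets, of which 3 differed in sign and 8 lay over 1 log2 unit apart. An annotation of the WBcel235 assembly held the gene of 20701 probe sets and was used for chromosome names only, with no coordinates, since the build behind the array's design is not given in the sources used here.

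Groups were taken from the sample titles. Differences are fed L1 minus mixed embryo, fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, no trend, not robust, 2-sided), with Benjamini-Hochberg adjusted p under 0.05 as the threshold over all genes tested, and SE is limma's moderated standard error. A second count required a log2 difference of at least 1. Lists were tested with camera, from limma, at its preset correlation of 0.01 and adjusted over the lists, with camera at an estimated correlation and with fry as alternatives, and members were also counted with p adjusted over the list alone. X-linked genes were set against autosomal genes by their medians, by an exact permutation of array labels on mean levels, and by camera. The range of 32 probe sets for bacterial and yeast transcripts that were not added to the samples served as background, and the highest of their values was 5.43. This level was chosen after the data were seen.

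The named genes followed a rule fixed before the data were examined. It took, among genes that passed limma and whose arrays did not overlap between stages, the 8 largest rises and the 8 largest falls with a gene class name and the 2 largest each way of any name. In every list it took the 2 largest changes in the list's main direction and the largest in the other, or the largest difference where no member passed, and every member of the dosage compensation list. The lists were early zygotic regulators, maternal and germline genes, cell cycle and DNA replication, condensin and cohesin, dosage compensation and sex determination, differentiation and Hox transcription factors, apoptosis and engulfment, cuticle collagens, moulting, intestine and digestion, lysozymes with saposins and C-type lectins, detoxification enzymes, neuronal function, neuropeptides and insulins, body wall and pharyngeal muscle, ribosomal proteins, ribosome biogenesis, mitochondrial respiration, core histones, starvation and fat metabolism, heat shock proteins, heterochronic genes, vitellogenins and sperm genes. Some lists were defined by the symbol of a gene family, and the pattern for ribosomal proteins also took in the replication protein A genes *rpa-1* and *rpa-2*.

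The steps were tested on simulated data with 200 of 17118 genes changed in the comparison of fed L1 with mixed embryos. Limma recovered 37.3% of genes changed by 0.5 log2 units, 91.0% of those changed by 1 and 98.5% of those changed by 2, with 5 false calls among 16918 unchanged genes. Camera found the shifted list and called 0 of 99 lists without a shift at an adjusted p under 0.05, with either correlation. The simulated genes varied independently of each other, so camera was not tested on correlated genes. The share of genes changed was also far below that found in the data. No pair of arrays was identical over all probe sets.

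Alternatives were another quantile normalization, centring each array on its median or on the ribosomal protein list, leaving out genes under the 25th or the 50th percentile of mean level, eBayes with trend and robust settings, array weights per group, the mean of a gene's probe sets, probe sets not designed to match related sequences, leaving out each array in turn, and, for the X chromosome, means, level-matched genes and leaving out lists. Leaving out genes at background on all arrays was added after the data were seen. Scan dates and array images were not analysed here.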

Results

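RNA levels of fed first-stage larvae (L1) and of embryos of mixed ages were measured in the wild-type *Caenorhabditis elegans* strain N2, the standard laboratory strain, whose hermaphrodites carry a pair of X chromosomes. Per the labels, L1 larvae came from eggs of bleached gravid adults that hatched over 24 h in M9 buffer at 20 °C. They were then given HB101 *Escherichia coli* at 10 mg/mL for 3 h, at a density of 10 worms per µL. Embryos were taken from bleached gravid adults grown on the same bacteria. Each stage had 3 Affymetrix arrays, and their number limits the precision. Values were RMA expression values on the log2 scale, with array medians of 6.08 to 6.10 for L1 and up to 6.04 for embryos. Across probe sets, which are not independent replicates, arrays of the same stage correlated at r = 0.9925 to 0.9967 and arrays of different stages at r = 0.7752 to 0.7905. The median SD between arrays of a stage was 0.11 for L1 and 0.12 for embryos, and no pair of arrays was identical over all probe sets. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. The embryo arrays were a re-analysis of arrays from an earlier series, so that array set and stage cannot be told apart. All L1 larvae had hatched in buffer and were then fed. Stage, hatching in buffer and feeding therefore cannot be told apart either, and a difference between the stages below includes all of them. The source label of the L1 samples names embryos, whereas their titles, descriptions and stage labels name L1 larvae.

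The stated purpose of the series was to set total RNA levels of fed L1 larvae against those of mixed embryos. The largest increases in L1 included genes of proteases and of enzymes that make fatty acids. The flavin-containing monooxygenase gene *fmo-2* rose by 8.13 log2 units (SE 0.09, n = 3 per stage), a 279.7-fold difference. The cathepsin B-like protease genes *cpr-1* and *cpr-4* rose by 7.31 (SE 0.09) and 6.88 (SE 0.10). The fatty acid elongase gene *elo-5* and the desaturase genes *fat-2* and *fat-6* rose by 7.05, 6.88 and 6.80. The largest decreases included genes of C-type lectins (*clec-266*, which fell by 7.40, SE 0.10, *clec-87*, which fell by 6.41, and *clec-91*, which fell by 6.07), of Skp1-related proteins, which are parts of ubiquitin ligases, and of the cuticle collagen *dpy-17*, which fell by 6.11 (SE 0.11).

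Among the Skp1-related genes, *skr-7* fell by 6.44 to a level on the L1 arrays within that of foreign control probe sets, *skr-13* fell by 6.35 and *skr-9* fell by 6.29. The last 2 were read by probe sets whose design allows matches to related sequences. The same holds for *clec-266*, *clec-87*, *clec-91*, *ttr-50*, *elo-5* and *fat-6*. The transthyretin-like gene *ttr-50* fell by 6.44. *phat-7* rose by 7.10 and the alcohol dehydrogenase gene *adh-1* by 6.43, the latter with the widest error of these genes (SE 0.27). Genes known by sequence name were also among the largest changes, with a difference of 7.61 in *C54D10.3* and -7.35 in *C01G6.3*, whose other probe set gave -4.85. The largest limma adjusted p among these genes was 7.15e-09. On the embryo arrays *fmo-2*, *phat-7*, *elo-5* and *C54D10.3* lay at or under 5.43, the highest value of 32 probe sets for bacterial and yeast transcripts that were not added to the samples, so the size of their change is a lower bound. The same holds for each change named in the text of a gene at this foreign control level in 1 of the stages.

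**Figure D1:**
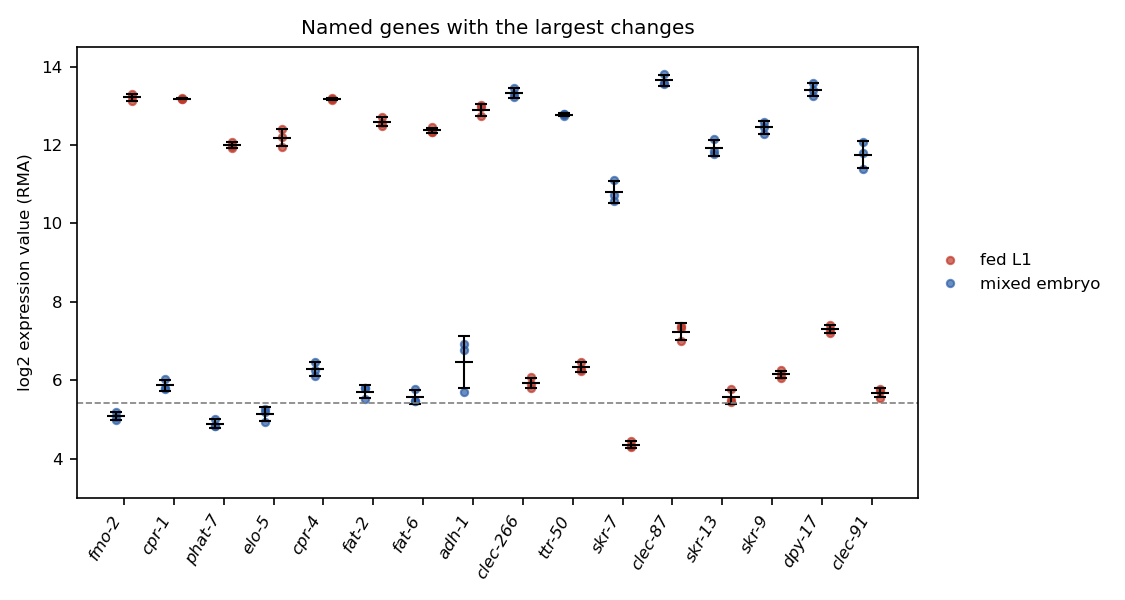
Log2 RMA expression values of the named genes with the largest increases and decreases, with each array as a point (red, fed L1; blue, mixed embryo) and the mean ± SD of 3 arrays. The dashed line marks 5.43, the highest value of the foreign control probe sets, and *fmo-2* went from 5.09 in embryos to 13.21 in L1.

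Of 17118 genes tested with limma, 11024 (64.4%) differed between the stages at a Benjamini-Hochberg adjusted p under 0.05, with 5685 higher and 5339 lower in L1. At least 2-fold differences were found for 5895 genes (34.4%), of which 2907 rose and 2988 fell. Differences of at least 4-fold held for 1331 rising and 1278 falling genes, and of at least 16-fold for 246 rising and 222 falling genes. The arrays of the stages did not overlap for 12089 genes (70.6%), against 10% by chance. Among 22548 probe sets, 7182 rose and 7080 fell. A total of 5473 genes lay at or under the foreign control level in both stages, and 1200 of these were among the genes called. The foreign control probe sets themselves differed by a median of 0.06 (range -0.10 to 0.26, L1 minus embryo). Small calls at this level cannot be told apart from such an offset in background.

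The balance of rises and falls depended on dim genes and on the scale. Without genes under the 25th percentile of level, 5006 genes were higher and 5127 lower in L1. Without genes at background on all arrays, an alternative chosen after the data were seen, 4763 were higher and 5041 lower. With each array centred on the ribosomal protein list, the median difference of all genes moved by -0.40, and 3732 genes were higher and 10199 lower, so that the share of higher genes among those called went from 51.6% to 26.8%. The hybridisation control transcript cre lay at 11.33 ± 0.08 on L1 arrays and 4.61 ± 0.09 on embryo arrays (SD, n = 3 per stage). The log2 difference between the 3′ and 5′ probe sets was 1.78 ± 0.24 in L1 and 1.80 ± 0.23 in embryos for actin, 0.63 ± 0.17 and 1.38 ± 0.46 for GAPDH, and 5.12 ± 0.15 and 4.88 ± 0.24 for ubiquitin, with no test of these differences. For catalase it was 3.79 ± 0.31 and 1.39 ± 0.06, but the 5′ probe set had means of 5.09 and 4.56, under the highest foreign control value of 5.43 in both stages.

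Genes were grouped in 24 lists fixed before the data were examined. With camera at its preset correlation between genes, 18 lists shifted, 8 towards L1 and 10 towards embryos. With a correlation estimated from the data, camera called 0 lists after adjustment and 13 at an unadjusted p under 0.05, and fry, which does not set a list against other genes, called 23. Members named below beyond the rule for named genes were chosen after their values were seen.

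Most listed genes of oocytes, of the dividing embryo and of its chromosomes were lower in L1. Of 32 maternal and germline genes, 30 fell, with a median of -3.22 (camera adjusted p = 2.71e-12; adjusted p = 0.0849 with an estimated correlation). Among them *mex-6*, which encodes a zinc finger protein of embryonic polarity, fell by 5.38 (SE 0.18) and *spn-4*, which encodes an RNA-binding protein of the early embryo, fell by 5.26 (SE 0.16). *skn-1*, a transcription factor gene of endomesoderm fate and later of stress responses, rose by 0.44 (limma adjusted p = 0.0167; its probe sets gave up to 0.98), a call lost without L1 replicate 3 (0.31), without embryo replicate B (0.37) and with ribosomal protein centring (0.04). The P granule helicase gene *glh-1* differed by -0.03 and did not pass. Of 31 cell cycle and DNA replication genes, 30 fell and 0 rose, with a median of -3.46 (camera adjusted p = 1.68e-14; adjusted p = 0.0849 with an estimated correlation). The B-type cyclin genes *cyb-3* and *cyb-2.2* changed by -5.32 (SE 0.10) and -5.26 (SE 0.13), and the kinesin gene *klp-7* differed by -0.05 and did not pass.

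Among 11 early zygotic regulators, 10 fell and the median was -1.92 (camera adjusted p = 0.000604; adjusted p = 0.342 with an estimated correlation). *pes-10*, one of the earliest genes transcribed in the embryo, fell by 4.69 (SE 0.15) to foreign control level, and the T-box gene *tbx-11* fell by 3.18 (SE 0.20). The exception was *med-1*, a GATA factor gene of endomesoderm fate, which rose by 0.39 at foreign control level in both stages and differed by -0.0044 with ribosomal protein centring. Of 14 condensin and cohesin genes, 12 fell, 0 rose and 2 did not pass, with a median of -1.36 (camera adjusted p = 2.11e-05; adjusted p = 0.0849 with an estimated correlation). The condensin subunit genes *capg-2* and *hcp-6* changed by -3.58 and -3.49, and *dpy-28* and the meiotic cohesin gene *rec-8* both differed by -0.15. Of 27 core histone genes, 20 fell, 2 rose and 5 did not pass, with a median of -2.12 (camera adjusted p = 1.46e-06; adjusted p = 0.0849 with an estimated correlation). *his-74* fell by 4.29, the H2A variant gene *htz-1* fell by 3.94 (its other probe set gave -1.31), and *his-37* and *his-35* rose by 0.74 and 0.47. Over the 8 histone genes with a probe set not designed to match related sequences, the median was -0.035 and camera made no call (adjusted p = 0.623). Adjusted over the list alone, the counts of rising and falling members were the same for each of these lists.

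Most listed regulators of embryonic tissues and most listed genes of cell death were lower in L1 too. In the list of 25 differentiation and Hox transcription factors, 17 fell, 4 rose and 4 did not pass, with a median of -0.95 (camera adjusted p = 0.000245; adjusted p = 0.0849 with an estimated correlation). The bHLH genes *hlh-14*, which acts in neuroblasts, and *hnd-1*, which acts in mesoderm, changed by -3.80 (SE 0.11) and -3.58 (SE 0.09), both to foreign control level. Those that rose were the intestinal GATA factor gene *elt-2* by 1.03 (0.27 in its other probe set and 0.65 as the mean of both), the Hox genes *mab-5* by 0.69 and *lin-39* by 0.38, and the epidermal GATA factor gene *elt-3* by 0.35. With ribosomal protein centring 2 of this list rose and 20 fell. In the apoptosis and engulfment list of 14 genes, 11 fell, 1 rose and 2 did not pass, with a median of -1.08 (camera adjusted p = 0.00152; adjusted p = 0.0849 with an estimated correlation). *ced-8* fell by 3.29 and *egl-1*, the BH3-only activator of programmed cell death, fell by 2.48 to foreign control level. *ced-7*, which encodes a transporter used in engulfment, rose by 0.46, while its other probe set gave -0.13 and the mean of both gave 0.16 with no call. Adjusted over the list alone, the counts in both lists were the same.

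Cuticle genes were more often lower than higher in L1, with the largest changes downward. Of 146 cuticle collagen genes, 57 fell, 23 rose and 66 did not pass, and adjusted over the list alone 55 fell and 23 rose. Their median was -0.17 (camera adjusted p = 0.004; adjusted p = 0.342 with an estimated correlation), and -0.29 when genes at background on all arrays were left out, an alternative chosen after the data were seen. Centred on ribosomal proteins, the collagen median was -0.57, with 9 rising and 109 falling. *dpy-17* and *dpy-14* changed by -6.11 and -5.94 (SE 0.12), and *col-103* rose by 3.80 (SE 0.12) from foreign control level in embryos. In the moulting list 11 of 15 genes fell, 2 rose and 2 did not pass, also when adjusted over the list alone, with a median of -1.30 (camera adjusted p = 0.0011; adjusted p = 0.0849 with an estimated correlation), and -2.38 without genes at background on all arrays. *noah-2*, a zona pellucida domain gene of the apical matrix, fell by 5.91 and *mlt-8* fell by 5.49. The kinase genes *nekl-3* and *nekl-2*, which act in cuticle shedding, rose by 1.12 and 0.96, and the protease genes *nas-37* and *nas-36* differed by 0.06 and -0.23 at foreign control level in both stages and did not pass.

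Most members of the intestine and of the starvation and fat metabolism lists were higher in L1, where stage and feeding cannot be told apart. Of 25 intestine and digestion genes, 24 rose, with a median of 3.70 (camera adjusted p = 2.62e-11; adjusted p = 0.0849 with an estimated correlation). Beside *cpr-1* and *cpr-4*, given above with their rises of 7.31 and 6.88, the exception was *asp-4*, a cathepsin D-like protease gene linked to necrotic cell death, which fell by 1.50 (SE 0.17). In the starvation and fat metabolism list of 21 genes, 17 rose, 2 fell and 2 did not pass, with a median of 0.77 (camera adjusted p = 0.00107; adjusted p = 0.0849 with an estimated correlation). The desaturase gene *fat-6* rose by 6.80 and the metallothionein gene *mtl-1* by 2.95 from foreign control level in embryos, while *cki-1*, which encodes a cyclin-dependent kinase inhibitor, fell by 1.71 and the glyoxylate cycle gene *icl-1* fell by 0.91. With ribosomal protein centring the median of this list was 0.37, with 14 rising and 4 falling. As background, the product of *fat-6* makes unsaturated fatty acids and that of *mtl-1* binds metals. For these lists the counts adjusted over the list alone were the same.

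The families of lysozymes, saposins and C-type lectins had 254 measured genes, of which 101 rose, 15 fell and 138 did not pass, and 100 rose and 13 fell when adjusted over the list alone. Their median was 0.16 (camera adjusted p = 0.000183; adjusted p = 0.0849 with an estimated correlation) and depended on the dim members. It was 0.57 without genes under the 25th percentile of level and 1.49 without genes at background on all arrays, 0.085 after another quantile normalization, and -0.24 with ribosomal protein centring, which lowers every difference alike and under which 71 rose and 124 fell. The saposin-like gene *spp-23* and the lysozyme gene *lys-4* rose by 5.92 (SE 0.13) and 5.85 (SE 0.08), against -7.40 in *clec-266*. On all embryo arrays 188 genes of these families lay at or under the foreign control level, and on all L1 arrays 154. Of 177 genes of cytochromes P450, glutathione S-transferases and UDP-glucuronosyltransferases, which modify foreign compounds, 105 rose, 21 fell and 51 did not pass, and adjusted over the list alone 108 rose and 21 fell. The median of these detoxification enzymes was 0.50 (camera adjusted p = 2.43e-06; adjusted p = 0.0849 with an estimated correlation). It was 1.02 without genes under the 25th percentile of level, 1.11 without genes at background on all arrays and 0.10 with ribosomal protein centring, under which 82 rose and 58 fell. *cyp-14A5* rose by 5.17 from foreign control level in embryos and *ugt-44* by 4.49, while *ugt-57* fell by 4.11 to foreign control level.

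**Figure D2:**
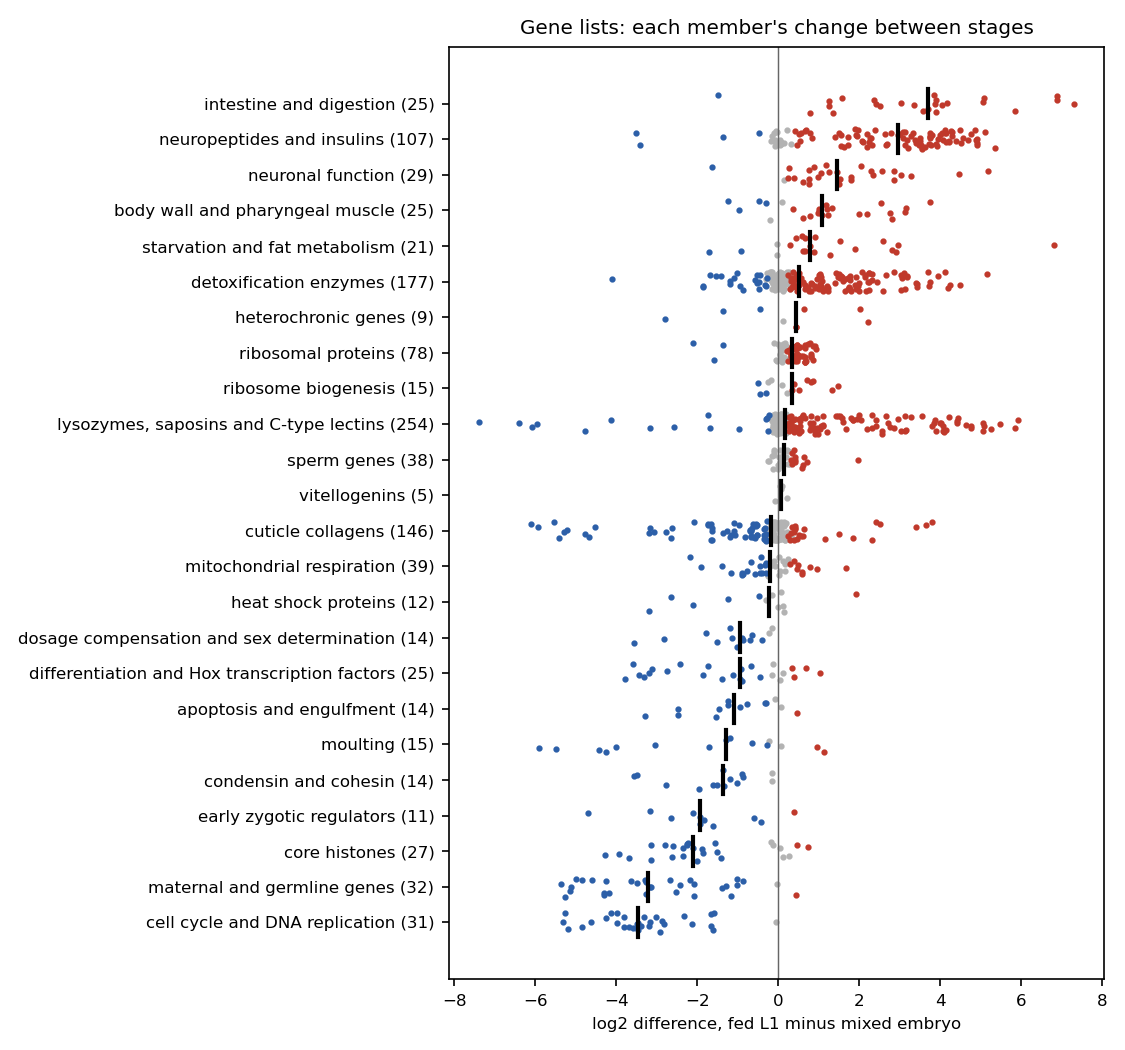
Log2 difference (fed L1 minus mixed embryo) of each measured member of the 24 gene lists, with red for genes that rose, blue for genes that fell, grey for genes that did not pass limma's test and black bars for list medians. Numbers in brackets are measured members, and medians ran from -3.46 (cell cycle and DNA replication) to 3.70 (intestine and digestion); the lysozyme, ribosomal protein, ribosome biogenesis, vitellogenin and sperm medians turned negative with ribosomal protein centring.

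Most listed genes of the nervous system and of muscle were higher in L1. Of 107 neuropeptide and insulin genes, 87 rose, 4 fell and 16 did not pass, and adjusted over the list alone 88 rose and 4 fell. The median was 2.96 (camera adjusted p = 3.15e-16; adjusted p = 0.0962 with an estimated correlation), and with ribosomal protein centring 81 rose and 17 fell. The neuropeptide genes *nlp-20* and *flp-17* rose by 5.34 (SE 0.15, from foreign control level in embryos) and 5.10 (SE 0.16). The members that fell were the insulin-like genes *ins-2* (-3.51, to foreign control level) and *ins-34* (-3.42) and the neuropeptide-like genes *nlp-31* (-1.36) and *nlp-33* (-0.48), known as antimicrobial peptide genes of the epidermis. Of 29 neuronal function genes, 27 rose, with a median of 1.44 (camera adjusted p = 3.71e-07; adjusted p = 0.0849 with an estimated correlation). *egl-3* and *egl-21*, which encode the convertase and the carboxypeptidase that process neuropeptides, rose by 5.18 (SE 0.10) and 4.46 (SE 0.09). *unc-119*, a chaperone gene expressed widely in neurons, fell by 1.65, and the synaptobrevin gene *snb-1* differed by 0.14 and did not pass. Of 25 body wall and pharyngeal muscle genes, 19 rose, 4 fell and 2 did not pass, with a median of 1.08 (camera adjusted p = 0.000476; adjusted p = 0.342 with an estimated correlation). The troponin genes *tnt-2* and *tni-3* rose by 3.75 (SE 0.10) and 3.15 (SE 0.17), and the other probe set of *tni-3* gave 1.92. The members that fell were *unc-45*, a myosin chaperone gene (-1.24), *tnt-3* (-0.96), *act-4* (-0.48) and *dim-1* (-0.31). Over the 13 muscle genes with a probe set not designed to match related sequences, the median was 0.99 and camera made no call (adjusted p = 0.125), and with ribosomal protein centring the muscle median was 0.68, with 17 rising and 6 falling. For the neuronal and muscle lists the counts adjusted over the list alone were the same.

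Most ribosomal protein genes rose by small amounts at high levels. The direction of the median turned only when arrays were centred on this same list, which fixes the outcome and cannot test the direction. Of 78 genes in this list, 50 rose, 3 fell and 25 did not pass, and adjusted over the list alone 52 rose and 3 fell. The median was 0.35 (camera adjusted p = 0.000332; adjusted p = 0.392 with an estimated correlation), and it was 0.20 after another quantile normalization and -0.050 by construction when arrays were centred on this same list, with 15 rising and 21 falling and no camera call (adjusted p = 0.0757). *rpl-4* and *rpl-23A.1* rose by 0.92 and 0.91. Those that fell were *rpa-1* (-2.099, and -0.50 in its other probe set) and *rpa-2* (-1.37), which encode subunits of replication protein A and not of the ribosome, and *rpl-41.1* (-1.58). Camera did not call the list of ribosome biogenesis genes (adjusted p = 0.232, and 0.566 with an estimated correlation), while fry called it towards L1 (adjusted p = 0.00348). The median of this list was 0.33. It was 0.21 without L1 replicate 2, -0.17 over probe sets not designed to match related sequences and -0.0625 with ribosomal protein centring, under which 5 rose and 6 fell. Of its 15 genes, 8 rose, among them *lpd-7* by 1.47 and the nucleostemin gene *nst-1* by 1.32, and 3 fell, *nol-10* (-0.50), *nol-14* (-0.46) and the fibrillarin gene *fib-1* (-0.30). The call of *nol-10* was lost without L1 replicate 1 (-0.44), without L1 replicate 3 (-0.45) and after another quantile normalization (-0.34).

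Of 39 mitochondrial respiration genes, 17 fell, 9 rose and 13 did not pass, with a median of -0.20 (camera adjusted p = 0.175; adjusted p = 0.488 with an estimated correlation) that was -0.12 without embryo replicate C and -0.081 after another quantile normalization. With ribosomal protein centring it was -0.60, with 3 rising and 26 falling and no camera call (adjusted p = 0.141). Paired forms of an ATP synthase subunit moved in opposite directions, with *asb-1*, known as the germline form, lower by -2.18 (SE 0.11) and *asb-2* higher by 1.67 (SE 0.10), and *asg-1* fell by 1.92. The heat shock protein list had a median of -0.23 and no camera call (adjusted p = 0.125, and 0.477 with an estimated correlation). Fry called this list towards embryos (adjusted p = 0.00163). Of its 12 genes, 1 rose, *hsp-43* by 1.93, and 5 fell. These were the inducible chaperone genes *hsp-16.41* (-3.18, SE 0.14), *hsp-70* (-2.65, SE 0.15) and *hsp-16.2* (-2.11, SE 0.11), and the endoplasmic reticulum chaperone genes *hsp-3* (-1.24) and *hsp-4* (-0.48). With ribosomal protein centring 11 of the 12 fell and the median was -0.63, again with no camera call (adjusted p = 0.118).

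The heterochronic genes, which time larval development, moved both ways, with a median of 0.44 over 9 genes (camera adjusted p = 0.55; adjusted p = 0.571 with an estimated correlation), and 0.28 without genes at background on all arrays, without genes under the 25th percentile of level or over probe sets not designed to match related sequences. Those that rose were *lin-41* by 2.22 (its other probe set gave 0.66), the nuclear receptor gene *daf-12* by 2.01, *lin-14* by 0.63, and *lin-29* and *lin-46* by 0.44 each (the last 3 at foreign control level in embryos, *lin-46* in both stages), and those that fell were *hbl-1* (-2.80), *lin-42* (-1.38) and *lin-28* (-0.46). The probe sets of *daf-12* gave differences from 0.05 to 2.01, and with ribosomal protein centring 2 of this list rose and 4 fell, with a median of 0.045. Of these ribosome biogenesis, respiration, heat shock and heterochronic lists, the counts were the same when adjusted over the list alone.

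Lists of genes from other life stages were included, and a difference between the stages does not show whether adult RNA was present in both. At or under the foreign control level lay 3 of 5 vitellogenin genes in each stage. Of 38 sperm genes, 14 lay there in L1 and 21 in embryos. None of the 5 measured vitellogenin genes, which encode yolk proteins of the adult intestine, passed limma's test over all genes or adjusted over the list alone. The largest difference was 0.21 in *vit-6* (SE 0.12, limma adjusted p = 0.161), whose other probe set gave -0.095. Without embryo replicate B it was 0.34 and passed, and without embryo replicate A it was 0.13. The vitellogenin median was 0.05 (camera adjusted p = 0.869; adjusted p = 0.897 with an estimated correlation), and -0.021 after another quantile normalization. It was 0.019 without embryo replicate A, 0.031 without L1 replicate 2, 0.11 without embryo replicate B, 0.095 without genes under the 25th percentile of level and 0.15 without genes at background on all arrays. It was -0.34 with ribosomal protein centring, under which 3 of the 5 genes fell. Of 38 sperm genes, 13 rose and 0 fell, also when adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.148; adjusted p = 0.488 with an estimated correlation). This direction turned with ribosomal protein centring, with a median of -0.26, 2 rising and 19 falling. The median was 0.051 after another quantile normalization, 0.24 without genes under the 25th percentile of level and 0.28 without genes at background on all arrays. The major sperm protein genes *msp-31* and *msp-40* rose by 1.96 (SE 0.14, from foreign control level in embryos) and 0.72 (SE 0.10), and both probe sets can match related members of this family.

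Genes of dosage compensation and sex determination were lower in L1 or did not pass. The dosage compensation complex binds both X chromosomes of hermaphrodites and lowers their transcription. Of 14 genes in this list, 12 fell, 0 rose and 2 did not pass, and adjusted over the list alone 13 fell. Their median was -0.95 (camera adjusted p = 0.000147; adjusted p = 0.0849 with an estimated correlation). The largest falls were outside the complex, in *sex-1* (-3.56, SE 0.09), a nuclear receptor gene on the X chromosome that counts toward the X signal, and *xol-1* (-2.84, SE 0.15), the switch gene that sets male fate, which went from 7.28 ± 0.33 to 4.45 ± 0.03 (SD, n = 3 per stage), within foreign control level. The other probe set of *xol-1* gave -0.84, and the mean of both -1.84. *dpy-30*, whose product also belongs to a histone methyltransferase complex, fell by 1.80 (SE 0.11), and *fox-1*, another X signal gene, fell by 1.15.

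The product of *dpy-30*, given above, belongs to the dosage compensation complex too. Among other members of the complex, *capg-1* changed by -1.51 (SE 0.10), *sdc-1* by -1.19 (SE 0.11), *mix-1* by -1.02 (SE 0.13), *dpy-26* by -0.89 (SE 0.16), *sdc-2* by -0.88 (SE 0.09), *dpy-27* by -0.66 (SE 0.10) and *sdc-3* by -0.40 (SE 0.10). The limma adjusted p of *sdc-3*, the largest among them, was 0.00424 (0.000613 for *dpy-26*). Their other probe sets gave -1.82 for *sdc-1*, -1.74 for *mix-1* and -0.37 for *dpy-27*, and *sdc-3* differed by -0.25 after another quantile normalization. *dpy-21* differed by -0.23 (limma adjusted p = 0.0696) and *dpy-28* by -0.15 (limma adjusted p = 0.223). With the mean of its probe sets *dpy-21* differed by -0.32 and passed, and after another quantile normalization it differed by -0.072. The probe sets of *dpy-28* gave -0.15 and 0.29, and after that normalization it differed by 0.015. *her-1*, the secreted signal of male fate, fell by 0.71 to foreign control level. *mix-1*, *dpy-26*, *dpy-28* and *capg-1* also belong to condensin and are members of that list. With ribosomal protein centring 14 of the 14 genes fell.

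**Figure D3:**
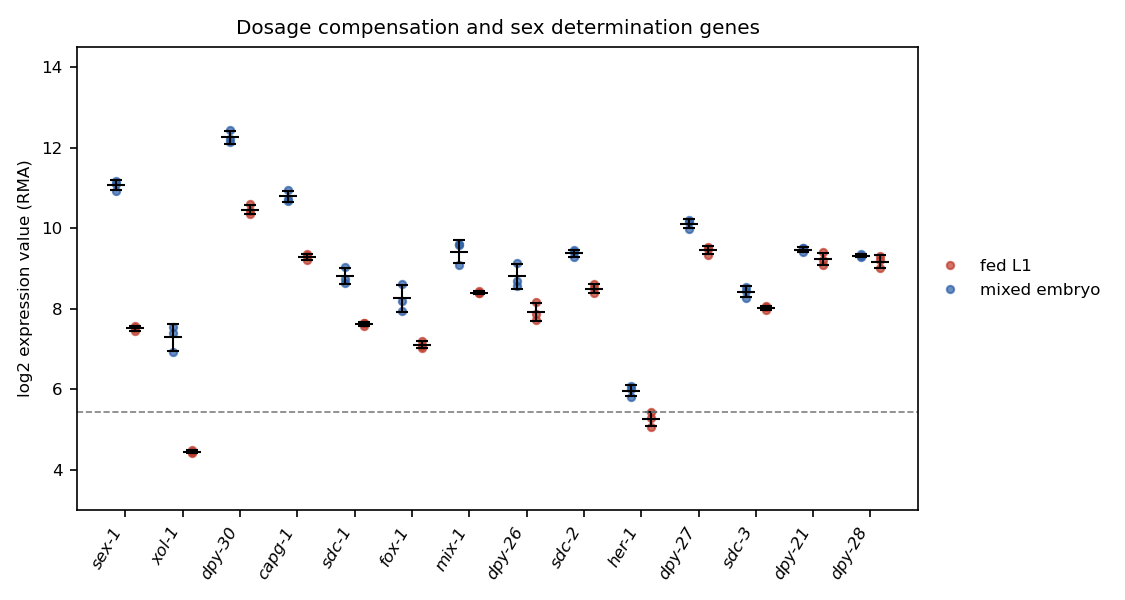
Log2 RMA expression values of 14 dosage compensation and sex determination genes, with each array as a point (red, fed L1; blue, mixed embryo) and the mean ± SD of 3 arrays. The dashed line marks the highest foreign control value, 5.43, and *sex-1* went from 11.06 in embryos to 7.51 in L1 while *dpy-28* went from 9.32 to 9.17.

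X-linked genes as a group had a median change 0.05 above that of autosomal genes. Camera did not call the difference, and the permutation test could not have called it with so few arrays. Among 2349 X-linked genes, 935 (39.8%) rose and 726 (30.9%) fell, and among 14715 autosomal genes 4734 (32.2%) rose and 4599 (31.3%) fell. The median difference was 0.10 for X-linked and 0.04 for autosomal genes. The mean level of X-linked minus autosomal genes was 0.17 ± 0.02 on L1 arrays and 0.02 ± 0.04 on embryo arrays (SD, n = 3 per stage; exact 2-sided permutation test p = 0.1, the smallest that the 20 assignments allow). Camera made no call for X-linked genes (p = 0.324; p = 0.572 with an estimated correlation). The difference of means was 0.14, and over genes above the median level the medians were 0.20 apart.

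Among the chromosomes, genes on chromosome I leaned towards embryos, with 640 of 2469 rising and 990 falling and a median of -0.07. Genes on chromosome V leaned towards L1, with 1574 of 4315 rising and 856 falling and a median of 0.11. Both chromosomes had a camera adjusted p of 0.0289 over the chromosomes and an adjusted p = 0.226 with an estimated correlation. The median level on chromosome V was 5.25 in L1 and 4.94 in embryos, under the highest foreign control value of 5.43. Foreign controls themselves leaned towards L1 by a median of 0.06, which limits the result for this chromosome. Ribosomal protein centring moves the medians of all chromosomes by the same -0.40, which makes that of chromosome V negative. Chromosomes were taken by gene from an annotation of the WBcel235 assembly, which placed 17072 genes.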

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

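The tests of the hybridisation controls were chosen only after the control values were seen, and the splits of the arrays were planned. Control transcripts outside the comparisons above differed between the stages. They are bacterial bioB, bioC and bioD and phage P1 cre, which the Affymetrix procedure adds to each labelled sample in rising amounts before hybridisation. In L1 minus embryo, bioB differed by 0.86, bioC by 2.29, bioD by 4.17 and cre by 6.71 log2 units, and this was picked out as a signal in data that no comparison uses, higher on L1 arrays than on embryo arrays. On L1 arrays the means of bioC, bioD and cre were 6.83, 8.79 and 11.33, above the highest foreign control value of 5.43, while bioB lay about that value, with a mean of 5.40 and 3 of its 6 probe sets above it. All 6 were higher on L1 arrays than on embryo arrays, by 0.52 to 1.09.

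*E. coli* RNA from the food does not account for this, because cre is a phage gene and its probe set with the smallest difference still gave 6.06. A difference in overall scaling is argued against by the order of probe sets within an array, which scaling keeps, since each control transcript had a higher mean percentile on L1 arrays, from 19.4 points for bioB to 75.2 for cre. The remaining technical explanation is that the embryo arrays may have had no control mix, or far less of it. On embryo arrays 17 of the 18 control probe sets lay within the range of the foreign controls, and on L1 arrays the transcripts rose in the order bioB, bioC, bioD and cre. If so, the array sets would differ in handling as well as in stage. No biological explanation of this pattern was tested.

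The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. With limma, the real split gave 11024 genes, 5895 genes at 2-fold and 14262 probe sets, and the highest among the other splits was 0 for each, so that 1 split of 10, the real one, reached each of these counts. At an unadjusted p under 0.05 the other splits gave 22 to 98 genes and 34 to 172 probe sets. For lists shifted with camera at its preset correlation, the real split gave 18 and the highest other split 18, and 5 of the 10 splits gave as many, so the number of lists called does not set the real split apart. Each of the other splits puts arrays of both stages on both sides in unequal numbers and so keeps part of the stage difference. The stage difference then also adds to the spread within each side, which lowers the limma counts of these splits. Their counts of 0 therefore do not show what a split without any stage difference would give.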

How the results depend on the processing

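All alternatives here were planned except leaving out genes at background on all arrays, which was chosen after the data were seen. No paired analysis was possible because the replicates are numbered 1 to 3 in L1 and lettered A to C in embryos and share no number. Leaving out each array in turn gave 10410 to 10887 genes changed, 5816 to 5959 at 2-fold, 13431 to 14015 probe sets, 18 lists each time and an X minus autosome median of 0.04 to 0.07. Without genes under the 50th percentile of level, 7304 genes and 9487 probe sets changed, with fewer tested. Of these genes 3274 were higher and 4030 lower in L1, so the balance turned towards falls. Ribosomal protein centring gave 3732 higher and 10199 lower genes by lowering all differences alike, which by construction turned the lysozyme and lectin median to -0.24, the ribosomal protein median to -0.050 (no camera call, adjusted p = 0.0757) and *med-1* to -0.0044. With an estimated correlation every called list lost its call at the same median: early zygotic (-1.92), maternal (-3.22), cell cycle (-3.46), condensin (-1.36), dosage compensation (-0.95), differentiation (-0.95), apoptosis (-1.08), collagens (-0.17), moulting (-1.30), intestine (3.70), lysozymes and lectins (0.16), detoxification (0.50), neuronal (1.44), neuropeptides (2.96), muscle (1.08), ribosomal proteins (0.35), histones (-2.12) and fat metabolism (0.77). Probe sets not designed to match related sequences left muscle at 0.99 and histones at -0.035 with no call, over fewer genes. Fry called ribosome biogenesis (0.33), respiration (-0.20), heat shock (-0.23), heterochronic (0.44) and sperm genes (0.14), at medians that camera did not call. The X minus autosome difference was 0.14 by means and 0.20 over genes above the median level, and the cause was not tested. Of 91 named genes under their alternatives, 896 results kept their call status, 8 lost and 5 gained a call, and 1 called gene turned. Direction was followed only for genes called with the main settings. Changes of sign in uncalled genes, such as *dpy-28*, are therefore not counted. Signal near background limits 5473 genes, whose differences are compressed and may include the background offset given above. Leaving them out gave 9804 changed genes, 4763 higher and 5041 lower in L1.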

Other observations

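The gene classes described here and the tests of the label and of heat shock were chosen only after the data were seen, except the test of oxidative response genes, which was set before its result was seen. Several gene classes outside the lists were higher in L1, among them neuropeptide receptors. Of 44 neuropeptide receptor genes of the npr class, 39 rose and 1 fell, with a median of 1.12 (camera adjusted p = 2.86e-07; adjusted p = 0.26 with an estimated correlation), and *npr-29* rose by 2.82. All 17 measured FMRFamide-type receptor genes of the frpr class rose, with a median of 1.09 (camera adjusted p = 0.000398; adjusted p = 0.281 with an estimated correlation). Of 42 potassium channel genes of the twk class, 30 rose and 1 fell (median 0.84, camera adjusted p = 0.000264; adjusted p = 0.252 with an estimated correlation). Of 20 acetylcholine receptor subunit genes of the acr class, 15 rose and 0 fell (median 0.81, camera adjusted p = 0.00368; adjusted p = 0.281 with an estimated correlation). Globin genes (glb) rose in 28 of 30 cases and fell in 0, with a median of 1.11 (camera adjusted p = 3.32e-06; adjusted p = 0.252 with an estimated correlation) and a rise of 2.59 in *glb-20* from foreign control level in embryos. Other classes rose too, with 11 of 13 P-glycoprotein genes (pgp, median 2.78, camera adjusted p = 0.000423; adjusted p = 0.252 with an estimated correlation), led by *pgp-3* at 5.41, and 10 of 12 galectin genes (lec, median 2.02, camera adjusted p = 0.000411; adjusted p = 0.252 with an estimated correlation), led by *lec-10* at 3.60. At or under the foreign control level in both stages lay 7 npr, 4 frpr, 13 twk, 6 acr, 2 glb and 2 pgp genes.

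Several other gene classes were lower in L1, among them an F-box class and the subunits of RNA polymerase II. Of 95 F-box genes of the fbxb class, 85 fell and 0 rose, with a median of -2.27 (camera adjusted p = 2.1e-17; adjusted p = 0.278 with an estimated correlation), and *fbxb-66* fell by 4.95 to foreign control level. Of 19 Skp1-related genes (skr), whose products bind F-box proteins, 14 fell and 4 rose (median -2.78, camera adjusted p = 0.000992; adjusted p = 0.281 with an estimated correlation). Another F-box class, fbxa, went the other way, with 77 of 171 rising and 20 falling (median 0.17, camera adjusted p = 0.0109; adjusted p = 0.281 with an estimated correlation), and its median turned to -0.22 with ribosomal protein centring. In both stages, 105 of the fbxa and 22 of the fbxb genes lay at or under the foreign control level. Near-identical members of these F-box and Skp1-related families can share probe signal. All 10 RNA polymerase II subunit genes (rpb) fell, with a median of -1.69 (camera adjusted p = 0.000332; adjusted p = 0.261 with an estimated correlation). Of 15 genes of TBP-associated factors (taf), 14 fell and 0 rose (median -1.24, camera adjusted p = 0.000115; adjusted p = 0.278 with an estimated correlation). Of 16 Mediator genes (mdt), 14 fell (median -1.45, camera adjusted p = 0.000219; adjusted p = 0.252 with an estimated correlation), and the 1 that rose was *mdt-15*, by 1.60, a regulator of fatty acid desaturase genes. Of 26 nuclear pore genes (npp), 22 fell and 0 rose (median -0.72, camera adjusted p = 0.000107; adjusted p = 0.354 with an estimated correlation). Among 165 classes of at least 10 genes, camera called 74, 39 towards L1 and 35 towards embryos, while with an estimated correlation it called 0 after adjustment and 29 at an unadjusted p under 0.05. Apart from fbxa, the classes named here kept the sign of their median with ribosomal protein centring, under which the medians were 0.73 for npr, 0.69 for frpr, 0.44 for twk, 0.41 for acr, 0.71 for glb and -1.12 for npp.

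The source label of the L1 samples names embryos. That these samples were embryos like those of the embryo arrays is argued against by the early zygotic and maternal lists, which had a median difference of -2.65 and lay lower in 41 of 43 genes. Among 1550 genes with an embryo level of at least 10, the 1st percentile kept 1.63% of the embryo level on L1 arrays and the lowest gene 0.593%, values that include background signal. For unhatched embryos with the RNA of the embryo arrays, a share well above these values is argued against, and a smaller share cannot be told apart from background. Embryos of other ages were not tested, and a wrong source label remains open.

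Some inducible heat shock genes were higher on embryo arrays, with -3.18 for *hsp-16.41*, -2.65 for *hsp-70* and -2.11 for *hsp-16.2*. They were picked from a list that fry called but camera did not (camera adjusted p = 0.125) and in which *hsp-43* rose by 1.93. Of 21 genes of the hsp class, 5 rose and 7 fell. An oxidative response of embryos to bleaching was predicted to raise its marker genes on embryo arrays, which was not seen. Their median difference was 0.64 towards L1, with *gst-4*, *gst-38*, *gcs-1* and *sqst-1* higher in L1 and *gst-10* at -0.14 without a call. This cannot decide the question, since stage or food could also raise these genes in L1 and no unbleached embryos were measured. A general heat shock response during embryo harvest stays open too, since *hsp-110* differed by -0.31 (limma adjusted p = 0.075) and *hsp-1* by 0.14, and the high levels of both might hide an induction. A difference between the stages in development was not tested apart from these, and array set and stage cannot be told apart.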
